A study of Homo sapiens with 4 samples.

How the data were processed

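The series holds 4 two-colour whole-genome expression arrays of human primary subcutaneous preadipocytes. Per the labels, each array carried cDNA of a preadipocyte culture kept with PBMC, labelled with Cy5, and of the media control of the same replicate number, labelled with Cy3, with 250 ng of cDNA as template for each dye. RNA was amplified and labelled by a commercial array service whose protocol is not given in the sources used here. No array had the dyes swapped.

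Per the file headers, the spot intensities were deposited as Agilent Feature Extraction 9.5.1.1 wrote them, with mean signals and local median backgrounds per channel, processed signals after the software's own background subtraction and its linear and lowess dye normalization, and flags for outlier spots and spots well above background. The deposited log10 ratio of each spot is Cy5 over Cy3 of the processed signals. The authors' series value table equals that log10 ratio spot by spot, with 1 empty cell in replicate 1, and its median was 0 on each array, so its scale, centring and direction are known. The first scanner file held 2 spots on a single line, which were separated before reading. All 4 arrays lay on 1 slide and shared 1 scan, and no spot was saturated.

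From the mean signals and median backgrounds, limma 3.58.1 in R 4.3.3 was used for normexp background correction with an offset of 50 on all spots and for loess within each array, in which the 1639 control spots and the outlier spots had a weight of 0. Control spots and outlier spots, between 403 and 724 per array, were then left out, and spots of the same probe were averaged, which took 43376 gene spots to 41000 probes. A probe was tested if it was well above background in all 4 Cy5 or all 4 Cy3 channels and had a ratio on at least 3 arrays. Where a gene had several such probes, the probe with the highest mean intensity over the arrays stood for it. Among 5186 genes with 2 or more tested probes, 2 had probes called in both directions. Few probes were called at all, so this count does not measure how well probes of a gene agree. Probes were named through the accessions, symbols and older symbols of a RefSeq gene table of assembly GRCh38.p14, which matched 26829 of 41000 probes; the others kept the name in the file. No coordinates are given, since the build behind those in the files is not stated. Probes of XIST and of Y-linked genes, 104 in all, were left out because the cells came from human donors.

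The log2 ratio of co-culture over media was tested in limma with lmFit, an intercept and eBayes, two-sided, with Benjamini-Hochberg adjustment over the 22779 genes tested and a threshold of 0.05. Both conditions of a replicate shared an array, so the ratio carries the pairing. After loess and between-array scaling, the deviations of both channels of the same array from their channel means correlated at 0.138, 0.384, 0.0982 and 0.324 across genes, which are not independent replicates. Ratios of different arrays correlated at 0.347 to 0.446 across genes. Fold changes are on the scale of log2 ratios after normexp with the offset, which understates the change of dim genes. A gene not above background in 1 condition on all arrays is given as a bound, the mean of its bright condition over the mean, per array, of the higher of its own signal and the lowest signal among probes above background. These bounds use channel values after loess and Aquantile scaling and are open to dye bias.

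Before the data were examined, 41 gene lists of inflammation, interferon response, fat cell and stromal biology, matrix, metabolism, stress and markers of other cell types were fixed, and each is reported. Lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over lists, with camera at an estimated correlation and fry beside it. A missing ratio took the gene's mean for these tests. The named genes follow a rule fixed at the same time. It takes the 14 largest increases and the 14 largest decreases among genes past the threshold that have a gene symbol and the same sign on all 4 arrays. It adds up to 4 such members of each list by size of the log2 ratio, and up to 2 members that did not pass with the highest mean intensity. Genes named only for being untested, and any others outside the rule, were chosen after their values were seen.

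The procedure was tested on simulated arrays with the real intensities, dye trends and backgrounds and 200 changed genes among the 22779 of this comparison. It called 54% and 56% of genes changed by a log2 ratio of -1 and 1, and 98% and 92% of those changed by -2 and 2. Of 22564 unchanged genes 11 were called, 6.47% of all calls, and the 1 shifted list and none of 40 others were called. The simulation holds no dye bias of single probes and no correlation between genes, which was estimated at 0.578 for the real metallothionein list. All members of its shifted list moved by a log2 ratio of 1. Its list result therefore does not cover smaller shifts or correlated lists. Alternatives tried were other background corrections, the processed signals, the value table, median centring, other intensity filters, every probe on its own, other variance models, array weights, channels without the pairing, and each replicate left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.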

Results

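Gene expression was measured in human primary subcutaneous preadipocytes, the fibroblast-like precursors of fat cells from the fat layer under the skin, kept either in media alone or together with peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes of blood. Each of 4 microarrays carried both conditions of a single experimental replicate, with the co-culture in the Cy5 (red) channel and the media control in the Cy3 (green) channel. Each array therefore gave a ratio of co-culture over media, and n = 4, apart from some tested genes with a ratio on only 3 arrays. The median Cy5 signal was 1840, 1744 and 1893 on replicates 1, 2 and 3 and 1054 on replicate 4, against Cy3 medians between 735.9 and 790.2. Replicate 4 also had fewer gene spots well above background, with 70.6% in Cy5 and 72.5% in Cy3, where the other replicates had 80.1% to 81.6%. The number of arrays limits the precision of every value. The labels call the arrays experimental replicates and do not say whether the cells came from separate donors, so the p-values measure the spread between these experiments. Whether the PBMC touched the preadipocytes, for how long, and in what state of activation is not given in the sources used here.

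The comparison asked which preadipocyte transcripts differed when PBMC were present. Among the largest fitted decreases in co-culture, the water channel AQP1 had a log2 ratio of -2.05 ± 0.30 (SE, n = 4), PJVK, of the gasdermin family, fell by 1.73 ± 0.17, C1QTNF3, which encodes a secreted protein related to adiponectin, fell by 1.65 ± 0.24, and the cytoskeletal septin SEPTIN8 fell by 1.63 ± 0.19, all above background in both conditions on 4 of 4 arrays. G0S2, an inhibitor of fat cell lipolysis, fell by 1.70 ± 0.11 on the log2 scale and had the lowest adjusted p of all genes tested (limma, adjusted p = 0.0145), and the zinc transporter SLC39A9 fell by 1.57 ± 0.22, both above background in co-culture on 3 arrays. ECSCR, a regulator of endothelial cell movement (-2.37 ± 0.35), LEP, which encodes the fat hormone leptin (-2.04 ± 0.23), CLIC6, of the chloride intracellular channel family (-2.03 ± 0.37), and PDK2, a kinase that restrains pyruvate dehydrogenase (-1.70 ± 0.17), were above background in co-culture on 1 array only, so the size of their ratios is uncertain. TEX35, HIPK4, ZNF200 and ZNF311 were well above background in media and on no array in co-culture, so they have only bounds. They were at least 2.28-fold (TEX35), 2.14-fold (HIPK4), 2.21-fold (ZNF200) and 2.29-fold (ZNF311) lower in co-culture. All 14 genes were lower on 4 of 4 arrays, as the rule for naming called genes required, with limma adjusted p from 0.0145 to 0.0487. Each of these 14 was measured by a single tested probe. The order among dim genes depends on the processing. The scanner software's processed signals differ in background subtraction, offset and dye normalization together. On them ECSCR had a log2 ratio of -3.63, HIPK4 of -2.97 and AQP1 of -2.13. Neither ECSCR (limma adjusted p = 0.0524) nor CLIC6 (limma adjusted p = 0.0652) passed there. CLIC6 passed in 4 of 16 alternative settings and ECSCR in 10. These include the settings with a replicate left out, in which no gene passed, and LEP passed in 12.

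The largest increases were in IFNE, which encodes interferon epsilon, with a log2 ratio of 1.57 ± 0.14 (SE, n = 4), and in CRYGS, a crystallin of the lens (1.44 ± 0.19), whose other probe gave 1.59 ± 0.22. LRRC71 (2.15-fold, SE 0.15 on the log2 scale), ARHGAP32 (1.09 ± 0.19), TTLL10 (1.07 ± 0.18), of the tubulin tyrosine ligase-like family, and the membrane fusion protein STX3 (1.06 ± 0.16) were also higher. The other 8 of the 14 largest increases lay among the brightest probes of the array, at a mean log2 intensity of at least 16. They were ZNF713 (1.34 ± 0.12), BCAS4 (1.26 ± 0.08), ADIPOQ, which encodes the fat hormone adiponectin (1.22 ± 0.13), VHL, part of the ubiquitin ligase that marks hypoxia-inducible factors for degradation (1.15 ± 0.12), POLR2J2 (1.11 ± 0.13), NACC1 (1.08 ± 0.11), the cyclophilin PPID (1.07 ± 0.13) and the fatty acid transporter SLC27A1 (1.07 ± 0.11). All 14 genes were higher on 4 of 4 arrays, again as the naming rule required, with limma adjusted p from 0.0179 to 0.0462. Of these 8 bright genes, 7 had other tested probes, 8 probes in all, and none of those passed the threshold, with log2 ratios between -0.51 and 0.14. The second ADIPOQ probe, for example, gave 0.09 ± 0.10, and the other VHL probe gave -0.06 ± 0.10. The brightest tested probe stood for each gene, so the other probes were dimmer by rule, but the rule does not set by how much. Their mean log2 intensity was 9.08 against 16.85 for ADIPOQ, 9.18 against 16.73 for BCAS4 and 12.2 against 16.3 for VHL. The gap was smaller for POLR2J2, at 14.92 against 16.76. Whether the bright and dim probes report the same transcript was not tested, so the bright ratios may not be those of the named genes. The 331 tested genes of this brightest class had a median log2 ratio of 0.291, above the -0.02 of all tested genes. ARHGAP32 also had 2 other probes, at -0.22 ± 0.10 and -0.28 ± 0.21, neither past the threshold.

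**Figure D1:**
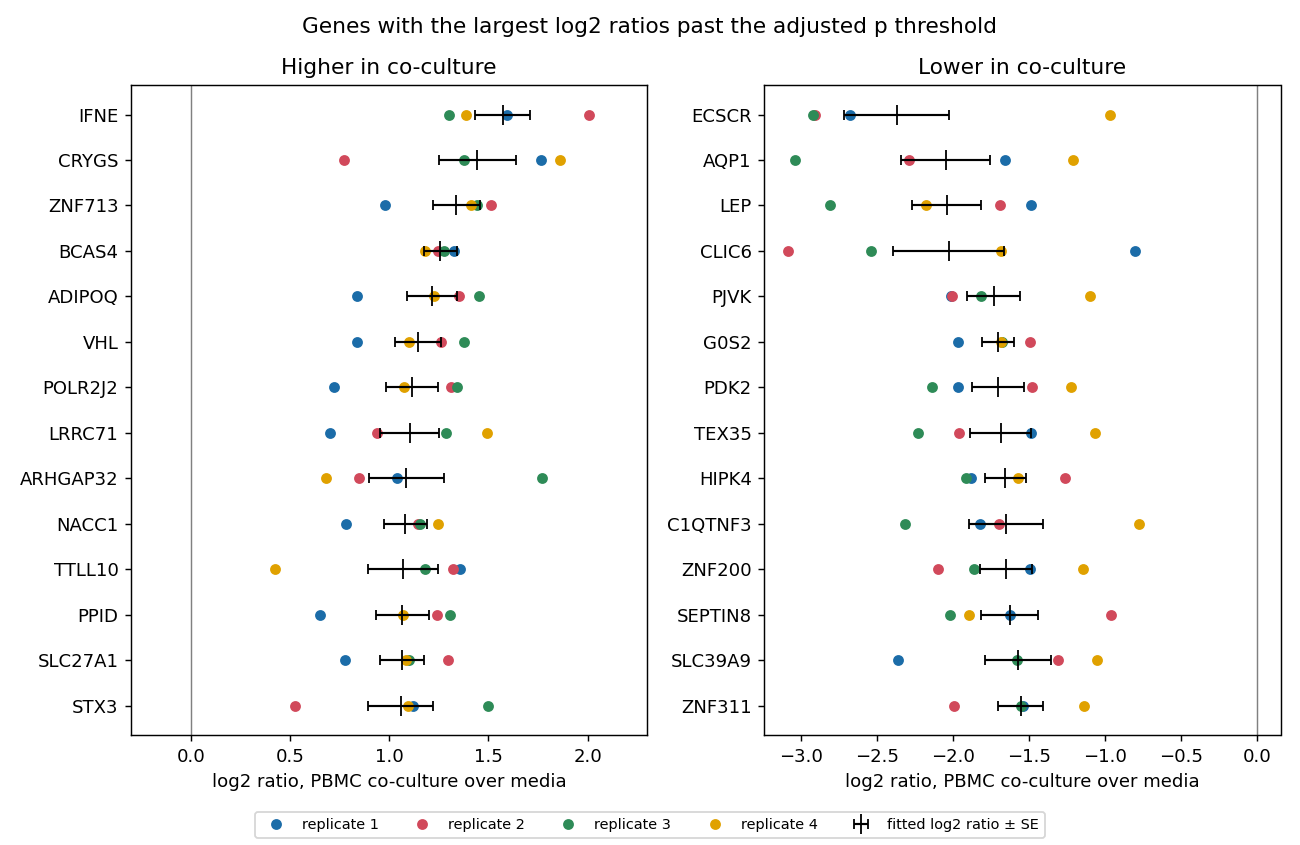
Log2 ratios of co-culture over media (x axis) for the 14 named genes with the largest increases (left) and decreases (right), one row per gene. Coloured points are the 4 replicates and black bars the fitted ratio with its SE. Every point lies on the same side of 0 as its gene's fitted ratio, which the rule for naming genes required. ECSCR on replicate 4, at -0.97, sits apart from its other values. The ratios of TEX35, HIPK4, ZNF200 and ZNF311 are drawn as measured although their co-culture signal was not above background.

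In all, 309 genes were higher and 476 lower in co-culture of 22779 genes tested (limma, Benjamini-Hochberg adjusted p under 0.05), of which 151 and 322 carry a gene symbol. The fitted change was at least 2-fold for 42 higher and 113 lower genes. Of the 113, 22 were above background on no array in co-culture and have only bounds, which for 7 of them lie under 2-fold, and 1 of the 42 has only a bound for the same reason in media. With both conditions required above background on every array 37 genes were at least 2-fold higher and 52 lower, and without loess 380 and 166. At an unadjusted p under 0.05 there were 2700 higher and 3442 lower genes. Another tested probe was at hand for 46 genes called higher below the brightest class, and its median log2 ratio was 0.09 where the called probes had 0.68. For 97 genes called lower, the other probe had a median of -0.27 where the called probes had -0.62. Because no array had the dyes swapped, a gene's dye bias cannot be told apart from its response to co-culture. No gene passed the threshold in limma when any 1 replicate was left out, with 4458 to 5714 genes at an unadjusted p under 0.05. Of the named genes POLR2J2, ARHGAP32, TTLL10, PPID, SLC27A1, ECSCR, CLIC6, MZB1, ACTG2, ANKRD37, GBP2, NQO1, CASP8, PDGFRB and PDGFD did not pass on the scanner software's own processed signals, with adjusted p from 0.0524 to 0.0769 and their signs kept. On these signals 141 genes were higher and 228 lower, and with arrays centred on their medians in place of loess 2057 were higher and 642 lower, which turned the share of calls that were higher from 39.4% to 76.2%.

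**Figure D2:**
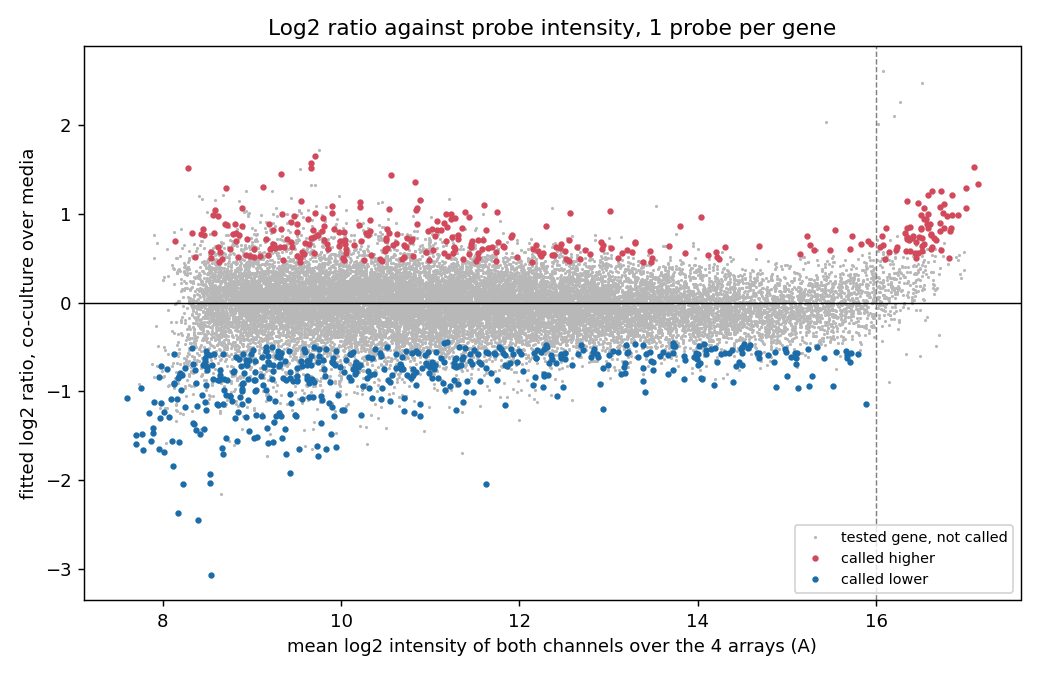
Fitted log2 ratio of co-culture over media (y axis) against the mean log2 intensity of both channels over the 4 arrays (x axis), with 1 point per tested gene. Grey points were not called, red points were called higher and blue points lower, and the dashed line marks an intensity of 16. To the right of it 66 genes were called higher and 0 lower.

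Of 41 gene lists fixed beforehand, the WNT pathway, with the secreted ligands, receptors and inhibitors of WNT signalling, passed as lower in limma's camera test against all other tested genes at the preset correlation (adjusted p = 0.0213), but not with an estimated correlation (adjusted p = 0.703) nor in fry (adjusted p = 0.0906), which asks whether a list's genes move, on balance, one way. Turning the sign of arrays gave at least as many called lists in 7 of 8 sign patterns, the real signs included, up to 6 lists, so a single called list does not stand out from other patterns. Of 22 tested members 19 had a negative ratio, with a median of -0.30 and array medians of -0.37, -0.13, -0.43 and -0.20 (n = 4). The receptor FZD1 fell by 0.88 ± 0.11 on the log2 scale (limma, adjusted p = 0.0351, lower on 4 of 4 arrays by the naming rule). Its other probe gave -0.45 ± 0.19 without passing. FZD1 was the 1 member called, over all genes and also adjusted over the list alone. Adjusting over a list alone does not compare it with other genes. Of all 22779 tested genes 6142 had an unadjusted p under 0.05, so a list can hold members that pass this way without standing out. The secreted WNT inhibitors DKK1 (-0.36 ± 0.13) and DKK3 (-0.32 ± 0.10) did not pass. No list was higher past the threshold in camera, in camera with an estimated correlation or in fry, and at an unadjusted camera p under 0.05 there were 12 lists in both directions together. By fry's test of change in either direction, which does not compare a list with other genes, 38 lists passed.

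Among adipocyte differentiation genes LEP and G0S2 were lower, as given above. ADIPOQ was higher on 1 probe of the brightest class and not past the threshold on its other probe, at 0.09 ± 0.10, while 19 of 22 tested members did not pass (median -0.03, camera adjusted p = 0.971). Hormone-sensitive lipase LIPE (0.20 ± 0.10) and the glycerol-3-phosphate dehydrogenase GPD1 (0.005 ± 0.10) were among these, though of GPD1's other probes 1 was lower, at -0.55 ± 0.09 (adjusted p = 0.0476 with every probe tested on its own). The same 3 genes passed when adjusted over the list alone. The fat cell genes FABP4, LPL, PLIN1 and RBP4 were not tested, since they were not above background on every array of either condition. Of 22 tested preadipocyte and stromal markers, the growth factor receptor PDGFRB fell by 0.60 ± 0.09 (limma, adjusted p = 0.0424), and 4 markers were lower adjusted over the list alone. The list's median was -0.10 (camera adjusted p = 0.276). THY1 (-0.02 ± 0.12) and ITGB1 (-0.06 ± 0.10), surface proteins of stromal cells, did not pass.

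Genes of inflammation were not called as groups. NFKBIA, which encodes the inhibitor of NF-kB and is itself a target of it, rose by a log2 ratio of 0.80 ± 0.11 (limma, adjusted p = 0.0356, higher on 4 of 4 arrays by the naming rule). It was the 1 called member of 17 tested NF-kB targets, of which 4 were higher adjusted over the list alone (median 0.12, camera adjusted p = 0.388). Of the 17, 7 had a negative ratio. TNIP1 (-0.33 ± 0.10, and 0.06 ± 0.14 on its other probe) and IER3 (-0.12 ± 0.10) did not pass. No inflammatory cytokine or chemokine was called. The cytokine IL6 had a log2 ratio of 0.43 ± 0.11 (adjusted p = 0.0881) and IL32 of 0.43 ± 0.17 (adjusted p = 0.182), and the neutrophil attractants CXCL5 (0.64 ± 0.18) and CXCL3 (0.44 ± 0.14, and 1.08 ± 0.25 on its other probe) did not pass either. The 10 tested inflammatory cytokines had a median of 0.19 and the 12 tested chemokines of 0.17, both with camera adjusted p = 0.169, and 1 chemokine passed adjusted over the list alone. CXCL8, CXCL9 and CXCL10 were not above background on any array in either condition.

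Interferon-response genes showed no shift as groups. GBP2, an interferon-induced GTPase, fell by 0.92 ± 0.16 (limma, adjusted p = 0.0452), the 1 called member of 22 in the interferon-gamma response (median 0.01, camera adjusted p = 0.967), and no member of 21 in the type I interferon response was called (median 0.06, camera adjusted p = 0.86). The other immune lists had no called member. They were MHC class I presentation (median -0.02, adjusted p = 0.967), MHC class II presentation (0.15, 0.176), complement and acute phase (-0.01, 0.967), cytokine and death receptors (0.00, 0.995), innate sensors (-0.06, 0.967), prostaglandin synthesis (-0.36, 0.124) and tryptophan and nicotinamide metabolism (-0.01, 0.773), each given as its median log2 ratio and camera adjusted p. Adjusted over the list alone, 4 prostaglandin synthesis genes and 2 genes of tryptophan and nicotinamide metabolism were lower. With every probe tested on its own, another SERPINA3 probe (complement and acute phase) was lower, at -2.04 ± 0.29 (limma adjusted p = 0.0416). The SERPINA3 probe used gave 0.10 ± 0.26. Another SECTM1 probe (interferon-gamma response) was lower at -1.47 ± 0.20 (limma adjusted p = 0.0401), against -0.03 ± 0.12 on the probe used. Across all lists, the median, the mean and the direction of the test did not share a sign for 10, all of them far from the threshold. They were the 2 interferon lists, MHC class I presentation, cytokine and death receptors, adipocyte differentiation, pan-leukocyte, NK, B cell and dendritic cell markers, and leukocyte-made cytokines.

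The contractile and TGF-beta response list held changes in opposite directions. ACTA2, the smooth muscle actin of myofibroblasts, fell by 1.14 ± 0.15 on the log2 scale (limma, adjusted p = 0.0351). ACTG2, another smooth muscle actin, rose by a log2 ratio of 0.62 ± 0.10 (limma, adjusted p = 0.0425). Each did so on 4 of 4 arrays, by the naming rule. On arrays centred without loess ACTA2 had a log2 ratio of -0.37 and did not pass. Of 19 tested members 17 were not called, among them TPM1 (0.42 ± 0.09) and TAGLN (0.04 ± 0.10), both actin-binding proteins. The 5 other probes of TPM1 gave between -0.26 and 0.32, none past the threshold. Adjusted over the list alone, 8 members were lower and 2 higher. The median was -0.27 (camera adjusted p = 0.115) and was 0.22 without loess. On the processed signals the list was lower past the threshold, with a median of -0.28 (adjusted p = 0.0315), as it was in 5 of 17 alternative settings, counting the value table, which holds the same ratios. With the main processing it had an adjusted p = 0.836 in camera at an estimated correlation of 0.447 and an adjusted p = 0.241 in fry. The pericyte and smooth muscle markers had a median of -0.29 (camera adjusted p = 0.115), with 2 lower and 1 higher over the list alone and none called over all genes, and passed in 1 of 17 alternative settings, with an adjusted p = 0.703 at an estimated correlation. No gene of the extracellular matrix list was called (26 tested, median -0.15, camera adjusted p = 0.544), with the collagen COL1A2 at 0.53 ± 0.13 and at 0.13 ± 0.20 on its other probe, and without loess that list was higher, with a median of 0.36. With the main processing the list had an adjusted p = 0.959 in camera at an estimated correlation of 0.413. Among 17 tested matrix proteases and inhibitors none was called, 4 were higher over the list alone, and the median was 0.07 (camera adjusted p = 0.276). Without loess that list was higher past the threshold as well, with a median of 0.48 (adjusted p = 0.0169), and with every probe on its own its median was -0.02. With the main processing it had an adjusted p = 0.703 in camera at an estimated correlation and 0.225 in fry.

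Cyclin E2, CCNE2, which drives entry into DNA replication, rose by a log2 ratio of 1.01 ± 0.12 (limma, adjusted p = 0.0342). It was the 1 called member of the cell cycle list, in which 21 of 28 tested members had a positive ratio (median 0.25, camera adjusted p = 0.0694, adjusted p = 0.733 with an estimated correlation). The list was higher past the threshold in 8 of 17 alternative settings, with a median of 0.27 (adjusted p = 0.0441) on the processed signals. Its array medians were 0.346, 0.225 and 0.19 on replicates 1, 2 and 3 and -0.0569 on replicate 4. MCM4 (0.27 ± 0.12) and CDC20 (-0.14 ± 0.12) did not pass. MT2A, a metallothionein that binds zinc and copper, rose by a log2 ratio of 0.81 ± 0.10 (limma, adjusted p = 0.0351), with 0.43 ± 0.12 on its other probe, which did not pass. Adjusted over the list alone 7 members of the metallothionein list were higher and 1 lower (12 tested, median 0.34, camera adjusted p = 0.0887, adjusted p = 0.776 at an estimated correlation of 0.578). The list passed in 4 of 17 alternative settings, its median running from 0.22 when centred within intensity classes, where it did not pass (adjusted p = 0.225), to 1.101 without loess. The 7 higher members had mean log2 intensities of 15.5 to 16.3, in or near the brightest class, whose ratios leaned upwards. Metallothionein transcripts are near-identical, so a probe can report more than a single gene of the family. Caspase 8, CASP8, a protease of death receptor signalling, rose by a log2 ratio of 0.71 ± 0.11 (adjusted p = 0.041) on a probe of the brightest class, whereas its other probes gave 0.10 ± 0.10 and 0.13 ± 0.25. The quinone reductase NQO1 fell by 0.63 ± 0.10 (adjusted p = 0.0424), the 1 called member of 15 in the oxidative stress response (median -0.08, camera adjusted p = 0.169). SLC7A11 of the same list did not pass on the probe used (-0.85 ± 0.19, limma adjusted p = 0.0667). Its other probe passed with every probe tested on its own, at -1.31 ± 0.13 (limma adjusted p = 0.0324). ANKRD37, a hypoxia-induced gene, fell by 0.88 ± 0.14 (adjusted p = 0.0425), the 1 called member of 21 in hypoxia and glycolysis (median -0.18, camera adjusted p = 0.427). The growth factor PDGFD was at least 1.73-fold lower (adjusted p = 0.0498), not being above background in co-culture on any array, and was the 1 called member of 22 secreted growth factors (median -0.05, camera adjusted p = 0.71). It passed in only 4 of 16 alternative settings, among them those with a replicate left out, in which no gene passed. On the processed signals it did not pass (limma adjusted p = 0.0575).

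The remaining metabolic and stress lists had no called member, apart from CASP8 among p53 targets and apoptosis (median -0.14, camera adjusted p = 0.37). Their medians and camera adjusted p were -0.16 and 0.0887 for cholesterol synthesis, -0.16 and 0.399 for the unfolded protein response, -0.15 and 0.773 for heat shock, -0.33 and 0.287 for the glucocorticoid response, -0.11 and 0.169 for oxidative phosphorylation and 0.03 and 0.525 for ribosomal proteins. Adjusted over the list alone, which does not compare a list with other genes, 5 p53 targets were lower and 2 higher. In the same way 4 glucocorticoid response genes were lower and 1 higher. The heat shock list had 3 lower and 1 higher, and the unfolded protein response 2 lower and 1 higher. On arrays centred without loess, the ribosomal protein list was higher, with a median of 0.74. With the main processing its camera adjusted p was 0.924 at an estimated correlation. Cholesterol synthesis was lower past the threshold in 2 of 17 alternative settings and oxidative phosphorylation in 1. At an estimated correlation with the main processing their camera adjusted p was 0.703 and 0.776.

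Markers of blood cells showed no joint rise in co-culture. The actin-bundling leukocyte protein LCP1 fell by 0.86 ± 0.08 (limma, adjusted p = 0.0281), the 1 called gene of 12 tested pan-leukocyte markers (median 0.04, camera adjusted p = 0.773). LCP1 was above background in co-culture on 3 arrays. The lymphocyte cytokine LTB fell by 0.89 ± 0.09 (adjusted p = 0.0287), the 1 called gene of 13 leukocyte-made cytokines (median 0.10, camera adjusted p = 0.773). Its probe had a mean log2 signal of 14.84 in media, without PBMC, and 13.95 in co-culture, so its source is uncertain. MZB1, a chaperone of antibody-making cells, rose by a log2 ratio of 0.57 ± 0.10 (limma adjusted p = 0.049), the 1 called gene of 10 B cell and plasma cell markers (median -0.002, camera adjusted p = 0.773). MZB1 passed in only 5 of 16 alternative settings, among them those with a replicate left out, in which no gene passed. On the processed signals it did not pass (limma adjusted p = 0.0524). The medians were -0.05 for T cell markers (camera adjusted p = 0.582), -0.03 for NK and cytotoxic markers (0.926), 0.07 for monocyte and macrophage markers (0.548) and -0.06 for dendritic cell markers (0.971), with no gene called. Adjusted over the list alone, 1 pan-leukocyte marker was higher and 1 lower (ITGAL, 0.37 ± 0.08, and LCP1), 1 monocyte and macrophage marker was higher (TYROBP, 0.42 ± 0.08, limma adjusted p = 0.0555 over all genes), 1 B cell marker was higher (MZB1), and of the leukocyte-made cytokines 1 was higher (TNFSF14, 0.34 ± 0.08) and 2 lower. CD163, a scavenger receptor of macrophages, was above background on 3 arrays in co-culture and 0 in media, and was not tested. ITGAL, TNFSF14 and CD163 were chosen after their values were seen. The pan-leukocyte gene PTPRC (CD45) and the monocyte gene LYZ were not above background on any array in either condition. Platelet markers had a median of 0.13 (camera adjusted p = 0.15) and erythroid markers of 0.07 (0.548). Of 6 tested endothelial markers (list median 0.09, camera adjusted p = 0.287) ERG was called higher, at a log2 ratio of 0.50 ± 0.08 (limma adjusted p = 0.0435). Its 2 other probes gave -0.68 ± 0.15 and -0.21 ± 0.09, neither past the threshold.

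**Figure D3:**
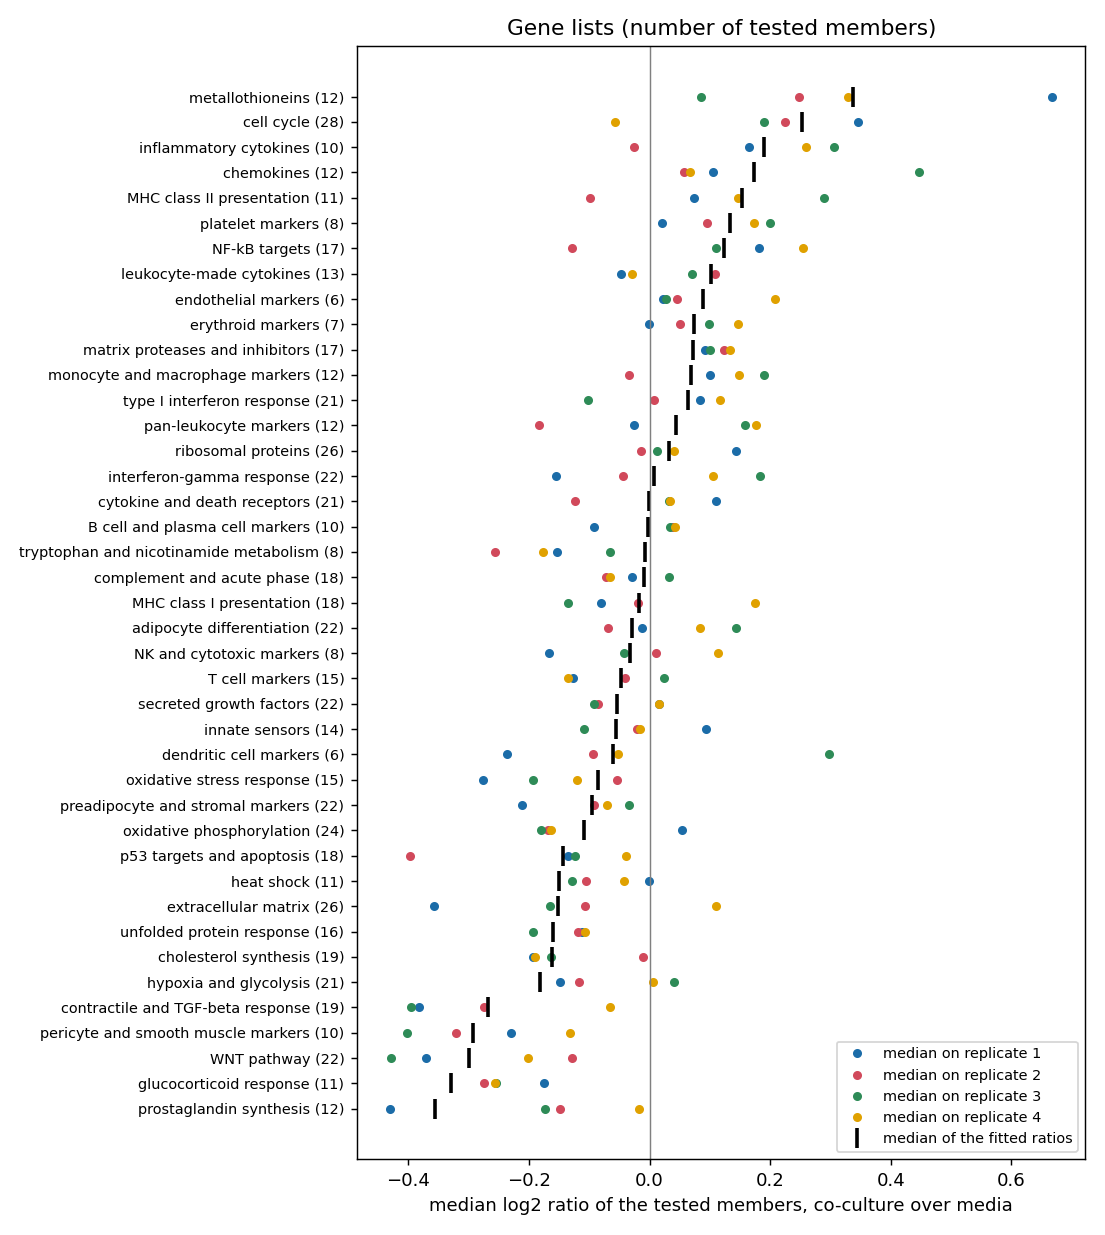
Median log2 ratio of co-culture over media of the tested members of each gene list (x axis), one row per list with its number of tested members. Coloured points are the medians on the 4 arrays and black marks the medians of the fitted ratios. The WNT pathway, at -0.30, is the list past the threshold, and its 4 array medians lie between -0.43 and -0.13. Its call was lost in camera at an estimated correlation (adjusted p = 0.703) and in fry (adjusted p = 0.0906).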

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

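Replicate 4 stood apart from the other arrays in 4 array measures. Its Cy3 background was 34 against 31.5 on the others, its ratio of median Cy5 to median Cy3 signal was 1.43 against 2.32 to 2.4, and the share of spots above background was 72.5% in Cy3 and 70.6% in Cy5 against at least 80.1%. Among the named genes, ECSCR had a log2 ratio of -0.967 on replicate 4 and -2.92 to -2.68 on the others. Of 94 sets of 4 values examined 11 had a value this far from the rest, where chance gives about 1 in 20, or 4.7.

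The other values that stood apart were medians of gene lists on single arrays. The chemokine median was 0.447 on replicate 3 and 0.0565 to 0.106 on the others, and the median of the unfolded protein response was -0.193 on replicate 3 and -0.119 to -0.107 elsewhere. Cholesterol synthesis had -0.0111 on replicate 2 against -0.194 to -0.164. Oxidative phosphorylation had 0.0532 on replicate 1 against -0.18 to -0.163, and B cell and plasma cell markers had -0.0927 on replicate 1 against 0.0345 to 0.0414. Endothelial markers had 0.208 on replicate 4 against 0.0222 to 0.0459.

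Control probes for E1A, a viral gene, gave signal that no comparison used. Whether spike-in RNA matching these probes was added is not stated, so what their signals and ratios mean stays open. Of 10 such probes 6 were above background in both channels on all arrays, and all 6 had a mean ratio above 0. The brightest had a median processed signal of 2160 in Cy5 and 1520 in Cy3, where negative control spots had 9.9 and 9.99, and its mean log2 ratio of Cy5 over Cy3 was 0.582 ± 0.388 (SD, n = 4).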

How the results depend on the processing

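The 4 gene counts stayed within 1.5 times without background subtraction, with a smaller normexp offset, with no intensity filter, with every probe on its own, with an intensity trend and robust prior, and with array weights. On the processed signals, and equally in the value table that holds their ratios, 141 genes were higher and 228 lower, with 1 list higher (cell cycle) and 2 lower (WNT, and contractile and TGF-beta response). With median centring in place of loess 2057 genes were higher, 380 of them at least 2-fold, and 4 lists were higher. The median of all tested genes was then 0.0908 against -0.0188, 76.2% of calls were higher against 39.4%, 19 of 41 list medians changed sign, and the extracellular matrix list turned to a median of 0.36 (camera adjusted p = 0.000184, over its alternatives up to 0.96). When both conditions had to be above background 52 genes were at least 2-fold lower, since genes dim in co-culture were no longer tested, and 2 lists were lower, as with no intensity filter. With every probe on its own 2 lists were higher. Without the pairing by array (8 channels as separate samples) 901 genes were higher and 1230 lower, with 2 lists higher. In 2 settings chosen after seeing the data, leaving out the brightest probes gave 175 higher genes, 22 of them at least 2-fold, and centring within intensity classes kept the gene counts within 1.5 times; both had 1 list higher and 2 lower, the same as on the processed signals. The cause of these shifts was not tested unless stated. Camera with an estimated correlation and fry each called 0 lists lower.

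Leaving out single replicates gave 0 genes in each of the 4 counts, with 4458 to 5714 genes at an unadjusted p under 0.05 in limma. The lowest adjusted p was 0.0582 to 0.118, and with fewer arrays fewer degrees of freedom remain. Of the called genes still tested at most 2 changed sign. They were called on these same arrays, so the kept signs are no separate support. These settings gave 0 to 2 lists higher and 1 to 2 lower. The WNT list was lower past the threshold in camera's preset test under each of the 17 settings that gave it a value (median -0.35 to -0.13). No named gene changed sign; 15 of 44 no longer passed on the processed signals or in the value table, with no intensity filter 7, and in each other setting with all 4 replicates at most 5. The slide as a random block was not run, since all arrays lay on 1 slide. Signal over background limits the ratios of genes dim in 1 condition to bounds.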

Other observations

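The tests of PBMC markers, of sign patterns and of other probes outside the brightest class, the offset on processed signals, the centring within intensity classes, and the limits of the bright and dim classes were chosen after the result was seen. Members behind some of the counts adjusted over the list alone follow, none of them past the threshold over all genes. They were chosen after their values were seen. Of all 22779 tested genes 6142 had an unadjusted p under 0.05, so such members do not set their lists apart. In the glucocorticoid response, the phosphatase DUSP1 (-0.54 ± 0.10, SE, n = 4), MAOA (-0.53 ± 0.13), the clock gene PER1 (-0.50 ± 0.11) and glutamine synthetase GLUL (-0.41 ± 0.10) were lower and the kinase SGK1 (0.35 ± 0.08) higher. Among p53 targets, ZMAT3 (-0.60 ± 0.15), SESN2 (-0.55 ± 0.13), SESN1 (-0.49 ± 0.12), the cell cycle inhibitor CDKN1A (-0.47 ± 0.10) and BAX (-0.43 ± 0.10) were lower, with other probes at -0.08 ± 0.12 for SESN1 and at -0.29 ± 0.09 and -0.01 ± 0.10 for BAX, while PMAIP1 (0.49 ± 0.13) was higher. In the prostaglandin list, prostacyclin synthase PTGIS (-0.85 ± 0.22), AKR1C3 (-0.46 ± 0.11), PTGS1 (-0.36 ± 0.08) and the phospholipase PLA2G4A (-0.35 ± 0.10) were lower.

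In the matrix and contractile groups, the TGF-beta-induced CCN2 (-0.74 ± 0.16), LMOD1 (-0.54 ± 0.11) and CALD1 (-0.50 ± 0.11) were lower over the list alone, and TIMP1 (0.50 ± 0.13), MMP9 (0.36 ± 0.09) and the urokinase receptor PLAUR (0.56 ± 0.15) were higher. The NF-kB targets SOD2 (0.73 ± 0.18), NFKBIZ (0.41 ± 0.08) and BCL2A1 (0.40 ± 0.11) and the chemokine CXCL2 (1.17 ± 0.23, limma adjusted p = 0.0549 over all genes) were higher, but the other CXCL2 probe gave -0.04 ± 0.13. The stromal markers ZNF423 (-0.70 ± 0.15), LUM (-0.59 ± 0.11) and S100A4 (-0.45 ± 0.10) were lower.

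Among the 331 tested genes of the brightest class 66 were called higher, 19.9% against 1.36% of all tested genes, and 0 lower. Another tested probe of 36 of these genes had a median log2 ratio 0.131 times that of the called probes (95% bootstrap interval -0.02 to 0.242), which is consistent with bias of single probes. That value was 0.139 (-0.0594 to 0.461) for 46 genes called higher at lower intensities, and 0.438 (0.366 to 0.611) for 97 genes called lower. It therefore does not set the bright genes apart from others called higher, while genes called lower kept more, and picking genes by the called probe lowers it in itself. Of the 36 other probes 10 lay in the brightest class, and their median mean log2 intensity was 12.5. Bias of single probes is thus not separated from the upward lean of the class. The median over all tested genes of the class was 0.291 (0.251 to 0.335), between the values named beforehand for and against an intensity trend left by loess, so that the trend stays open as part of the pattern. After centring within intensity classes 20 of the 66 were still called and their median fell from 0.808 to 0.505; a response of these genes to co-culture stays open.

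Of 113 genes at least 2-fold lower 92 had a mean log2 intensity below 10, and 23 of the 92 were above background on no array in co-culture by the tested probe alone. On the processed signals their median log2 ratio was 1.44 times the main one (1.31 to 1.5). That meets the bound set beforehand against background handling, but the bound was wrong, since the processed signals carry no offset and so enlarge dim ratios in themselves. With the offset of 50 added to them the quotient was 0.896 (0.828 to 0.913), and without background subtraction it was 1.07 (1.02 to 1.08). Only 29 of the 92 were above background in co-culture on all 4 arrays, so with signals this near the background its handling stays open for the size of the decreases. Only 2 of these genes had another tested probe, with a quotient of -0.0387, too few to test the bias of single probes, which cannot be told apart from a response to co-culture.

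RNA of PBMC carried into the lysate could raise leukocyte transcripts among the 309 genes called higher. The 63 tested markers of PBMC types had a median log2 ratio of -0.024 (-0.0561 to 0.071), below 0.35, which is 0.5 times the median of genes called higher. Of these markers 1 was called higher and 1 lower, and PTPRC and LYZ were not above background on any array. The 63 were those tested of 103 on the array, and the interval resamples markers, not arrays. Some, like LAT and CD4 (mean log2 intensities 14.11 and 14), were bright in both conditions, so carried RNA could raise their ratios little. The median is thus a weak test. The absent signal of PTPRC and LYZ argues more directly against carried RNA as the source of the increases as a set. A small share of such RNA stays open, since CD163 was above background in co-culture on 3 arrays and in media on 0, and TYROBP and ITGAL had ratios of 0.42 and 0.37.

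Turning the sign of arrays gives 8 patterns, too few for a share under 0.05. The real signs gave 785 called genes and the highest other pattern 0, and 155 genes with at least a 2-fold change against 0, so 1 of 8 patterns gave as many in both. No array had the dyes swapped, so a dye bias of single probes shared by the arrays would also give more calls with the real signs. The contrast cannot tell such a bias from a response to co-culture. For lists 7 of 8 patterns gave as many as the real 1, the highest other being 6.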
